A study of Mus musculus with 3 samples.

How the data were processed

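Total RNA of the cytosolic fraction of C57BL/6J bone-marrow-derived macrophages was depleted of ribosomal RNA and sequenced in 3 libraries, made per the labels from 1 µg of RNA with a size range of 250 to 400 bases. Per the labels the libraries are biological replicates 1, 2 and 3 of separate samples under one treatment. They share a donor label, which may stand for the strain, so it is not given here whether the cultures came from different animals. All 3 form 1 group, no control group was used here, and no comparison between groups or paired analysis was made.

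Each library had 3 deposited tables. The deposited gene table holds expected counts, which need not be whole, with TPM, FPKM and bounds of TPM per gene; per the file headers its column layout is that of RSEM. A deposited transcript table holds estimated counts and TPM made from the same transcriptome alignments, and is called alignment-based here. Another deposited transcript table holds estimated counts and TPM made from the reads and an index without an alignment file, and is called read-based here; per the file headers its layout is that of kallisto. The deposited FPKM values are per kilobase of effective length and scaled to library depth. Accompanying text files name the mm10 build and annotation M21. Names and versions of the aligner and quantifiers are not given in the sources used here. The deposited TPM sums to the same total over all entries of a table, so it depends on every abundant RNA in a library.

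Rows that name no gene were kept out of library sizes and tests. They are 96 ERCC spike-in rows with 0 counts, 26248 rows with numeric names that held at most 2 counts in a library, and 1 phiX row. They held 0.356%, 0.125% and 0.104% of all expected counts in replicates 1, 2 and 3. The remaining 55536 rows all matched the annotation, and gave 38197192, 46327891 and 38685666 expected counts. Of 347 gene symbols in the lists 346 matched a gene of annotation M21; Norad did not and is not reported.

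Genes were called detected at a TPM of 1 or more in all 3 libraries. Levels were compared on the log2(TPM + 1) scale, which understates ratios of low genes. Replicate spread was the common biological coefficient of variation from an intercept-only edgeR model (edgeR 4.0.16 in R 4.3.3) on expected counts rounded to whole numbers, with TMM normalization and filterByExpr. Libraries were compared in pairs by chi-square over genes with at least 10 counts. The ratio of 24 gene pairs was tested against 0 with limma 3.58.1, two-sided, with 5000 random pairs of detected protein-coding genes added to the fit for the variance prior and Benjamini-Hochberg adjustment over the 24 pairs. One pair and some list members are not reported here. DESeq2 1.42.0 gave alternatives. Values are given as mean ± SD of 3 libraries, and pair ratios as mean ± SE.

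The level of a gene list is the median over its members of mean log2(TPM + 1), set among 10000 random lists of the same size drawn from annotated protein-coding genes. The spread of a list is the median SD of its detected members among 10000 random lists of detected genes matched on mean level in 20 bins. Both percentiles describe these libraries and are not p-values, since genes are not replicates. The 24 lists, the 24 pairs, the 25 genes for isoform shares, the tests and most alternatives were chosen before the data were examined. Genes were named by a fixed rule: in each list the 4 members with the highest mean TPM and the first 4 in alphabetical order of those detected in no library, the 10 nuclear protein-coding genes with the highest mean TPM, the 10 genes with the largest SD of log2(TPM + 1) at a mean TPM of 10 or more, and all genes of the pairs and of the isoform list. Other named genes were chosen after their values were seen, namely Rn7s1, Rn7s2, Rn7sk, Ifnb1, Gm49369, Airn, and in the closing section Gm26917, Gm12895, Gm12896, Gm23935, Gm24245, Gm24270, Slc13a3, Rgs1, Tnfsf9 and Cxcl1.

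The deviation of a library is its log2 TPM minus the mean log2 TPM of the other 2, less the median of that difference over 9106 detected nuclear protein-coding genes. It was added after the data were seen, with TMM-normalized counts and the read-based table as alternatives. Other alternatives were thresholds, pseudocounts, FPKM, filters, TPM rescaled over nuclear protein-coding genes, the background and bins of the random lists, and each library left out in turn.

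The scripts were tested on simulated data. With counts for 12752 genes drawn at a coefficient of variation of 0.2, edgeR returned 0.199. Among 200 simulated pairs per size, limma gave an unadjusted p under 0.05 for 7% with no difference, 48.5% at a log2 difference of 0.5, 97% at 1 and 100% at 2. All simulated genes had the same coefficient of variation, so these rates do not cover pairs that vary more than the random pairs. Among 200 random lists 4.5% reached the 95 percentile of spread, and 96% did once the SD of their members was multiplied by 2. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for the rest.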

Results

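Ribosomal-RNA-depleted total RNA of the cytosolic fraction was measured in 3 libraries of bone-marrow-derived macrophages, cells grown from mouse bone marrow into macrophages in culture, from the C57BL/6J strain. The cells had been exposed to 100 ng/ml Lipid A for 12 hours, kept without it for 12 hours, and then given the same dose again, this time for 40 minutes. Lipid A is the part of bacterial lipopolysaccharide that the receptor Tlr4 senses. The 3 libraries are biological replicates of this 1 group. Untreated cells, cells stimulated once and other cell fractions were not analysed here, so the values are levels, not responses to the second stimulus. Expected counts on annotated genes summed to 38197192 in replicate 1, 46327891 in replicate 2 and 38685666 in replicate 3. At these depths 3 counts, the upper 95% confidence bound for a count of 0, equal 0.0785, 0.0648 and 0.0775 CPM, which covers counting error only. Gene positions are those of the mm10 build and annotation M21.

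In the gene tables a small number of short structured RNAs took most of the TPM. Rn7s1 (chromosome 12, 69159295 to 69159594, plus strand) and Rn7s2 (chromosome 12, 69361182 to 69361481, minus strand) encode the 7SL RNA of the signal recognition particle, and together held 57.9% ± 4.45 of TPM (SD, n = 3). Their share was 8.50% ± 1.46 of expected counts and 17.2% ± 5.46 of TPM in the read-based table, and the split between these near-identical copies is uncertain. The 7SK RNA, which restrains transcription elongation, held 4.796% ± 1.41 of TPM from Rn7sk. Nuclear protein-coding genes held 29.7% ± 3.17 of TPM, but 86.8% ± 1.13 of expected counts, since TPM divides by effective length. Protein-coding genes named Rpl or Rps with a number held 1.46% ± 0.156 of TPM. This naming rule misses some ribosomal protein genes and takes in a few other genes. Long non-coding RNAs held 0.963% ± 0.335 and mitochondrially encoded RNAs 0.417% ± 0.168. TPM values of mRNAs below are therefore shares of a total that in the gene tables is mostly 7SL RNA.

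TPM was 1 or more in all 3 libraries for 9648 of 55536 annotated genes, and for 9118 of 22028 protein-coding genes. The most abundant nuclear protein-coding transcripts were those of the ferritin subunits that store iron, Fth1 at 18035 ± 1394 TPM (SD, n = 3; chromosome 19, 9980598 to 9985098) and Ftl1 at 7358 ± 487 TPM. The acute-phase protein gene Saa3 (chromosome 7, 46711998 to 46715700) came after them at 4908 ± 2339 TPM, with 5789, 2257 and 6679 TPM in replicates 1, 2 and 3. The chemokine gene Ccl5 (chromosome 11, 83525778 to 83530518) followed at 4714 ± 666 TPM. Next came Tmsb4x at 4508 ± 761 TPM, which encodes an actin-binding peptide, and the lysosomal Psap at 3603 ± 264 TPM. B2m, the light chain of MHC class I, had 3464 ± 452 TPM and the cytoskeletal Actb 3351 ± 609 TPM. Lyz2, the macrophage lysozyme, had 3020 ± 549 TPM. The lysosomal protease gene Ctsd completed the top 10 at 2509 ± 12.7 TPM; it overlaps Gm49369 on the same strand (chromosome 7, 142371096 to 142382667), and reads of the shared part could be counted for either.

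Macrophage genes were high and markers of other blood and stromal cells were near 0. All 20 macrophage identity genes were detected, with a median level of 7.08 on the log2(TPM + 1) scale, above all of 10000 random lists of 20 protein-coding genes. Lyz2, Ctsd, the lysosomal protease gene Ctsb at 2070 ± 268 TPM and Fcer1g, a signalling subunit of Fc receptors, at 1286 ± 63.9 TPM led the list. Of 11 neutrophil markers 3 were detected, namely Csf3r at 36.7 ± 5.35 TPM, S100a9 at 4.55 ± 0.604 TPM and S100a8 at 3.22 ± 0.888 TPM, while Cxcr2, Elane, Ltf and Ly6g were detected in no library. Csf3r, the receptor for granulocyte colony-stimulating factor, is also expressed by monocytes and macrophages. Among B cell markers Cd22 reached 7.51 ± 2.41 TPM and Cd79b 1.53 ± 0.365 TPM, and Cd79a, Ebf1 and Ighm were below 1 TPM in every library. Cd4 at 17.9 ± 2.39 TPM was the only detected T and NK cell marker of 11, with Cd2, Cd3d, Cd3e and Cd3g below 1 TPM. Batf3 at 1.92 ± 0.692 TPM was the only dendritic cell marker of 10 detected in all libraries; Clec9a, Cd209a, Ccr9 and Flt3 were detected in none.

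None of 10 mast cell and eosinophil markers was detected in any library, Cpa3, Epx, Fcer1a and Kit among them. Kdr at 5.16 ± 2.59 TPM and Vwf at 3.96 ± 1.11 TPM were detected among 11 stromal and endothelial markers, whereas the collagen genes Col1a1, Col1a2 and Col3a1 and the endothelial cadherin gene Cdh5 were not detected in any library. Of 10 erythroid markers only Tfrc, the transferrin receptor that many cell types carry, was detected, at 47.0 ± 5.88 TPM; Alas2, Car1 and Epor were below 1 TPM in each library. The median level of these 7 lists of other cell types lay between the 18.1 and the 44.5 percentile of random protein-coding lists.

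**Figure D1:**
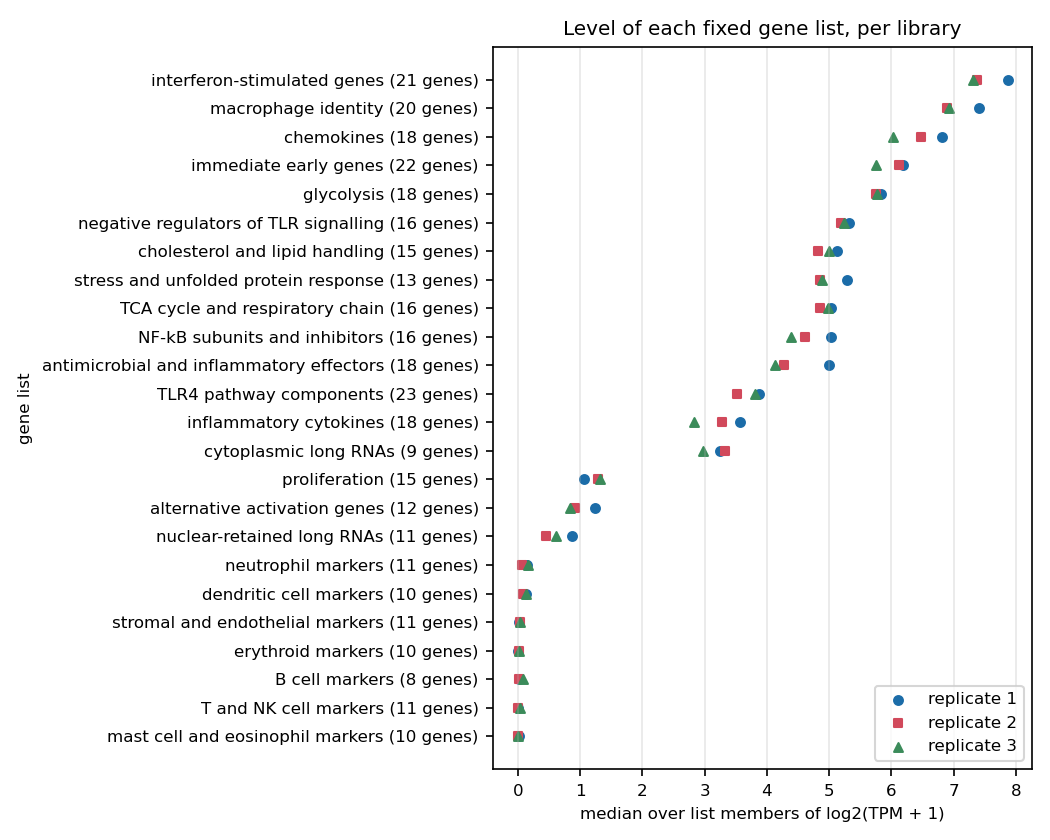
Median over the members of each of 24 gene lists of log2(TPM + 1), one symbol per library; the number of matched genes stands beside each name. Macrophage identity (7.08 over the libraries) and interferon-stimulated genes (7.44) lie at the upper end, and the 7 lists of other cell types lie near 0.

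Immediate early genes, which cells transcribe within minutes of a stimulus, were abundant 40 minutes after restimulation. Of 22 members 20 were detected, with a median level of 6.12 (log2), above all random lists. Zfp36 (chromosome 7, 28376784 to 28380253), whose product destabilises cytokine mRNAs, had 399 ± 92.5 TPM, Junb 194 ± 24.2 TPM, Egr1 173 ± 47.9 TPM and Klf6 173 ± 47.0 TPM (SD, n = 3). Fosb and Fosl1, partners of Jun in the AP-1 transcription factor, were below 1 TPM in each library. Egr1 exceeded its relative Egr2 by 4.43 ± 0.13 on the log2 scale (SE; limma, adjusted p = 1.03e-08 over the 24 pairs, higher in 3 of 3 libraries). Fos at 82.9 ± 9.60 TPM and Jun at 61.1 ± 11.0 TPM were closer, with a log2 ratio of 0.44 ± 0.16 (limma, adjusted p = 0.0267) that was positive in 2 of 3 libraries. Leaving out replicate 3 gave 0.26 for that ratio (limma, adjusted p = 0.153) and leaving out replicate 2 gave 0.39 (limma, adjusted p = 0.0782). Dusp1 exceeded Dusp2, both phosphatases of MAP kinases, by 0.67 ± 0.11 (limma, adjusted p = 0.000460, 3 of 3 libraries).

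All 16 genes of NF-kB subunits and inhibitors were detected, with a median of 4.76 (log2), above all random lists. Genes that do not encode subunits led. Nfkbia, which encodes the NF-kB inhibitor IkB-alpha (chromosome 12, 55489410 to 55492647), had 348 ± 104 TPM, the ubiquitin-editing enzyme gene Tnfaip3 137 ± 50.9 TPM, Nfkbiz 99.9 ± 37.0 TPM and Tnip3 86.1 ± 27.5 TPM. Nfkbia exceeded Nfkbib by 3.60 ± 0.10 on the log2 scale (limma, adjusted p = 1.03e-08) and Tnfaip3 exceeded Cyld, another deubiquitinase, by 3.42 ± 0.17 (limma, adjusted p = 2.80e-07), both in 3 of 3 libraries. The subunit genes Nfkb1 at 28.0 ± 4.60 TPM and Rela at 21.2 ± 1.57 TPM differed by 0.37 ± 0.10 (limma, adjusted p = 0.00911, 3 of 3 libraries). In the read-based quantification that difference was 0.07 (limma, adjusted p = 0.505), and without replicate 1 it was 0.30 (limma, adjusted p = 0.0685).

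Among inflammatory cytokines the transcripts of Tnf were abundant and those of Il6 scarce. Of 18 inflammatory cytokine genes 13 were detected and 5 were detected in no library, among them Csf2, Csf3, Il12a and Il23a. The median level was 3.28 (log2), at the 99.9 percentile of random lists of annotated protein-coding genes and at the 51.9 percentile of lists of detected ones, to which 5 of its 18 members do not belong. Tnf (chromosome 17, 35199381 to 35202007) had 651 ± 251 TPM, Il1b 123 ± 37.1 TPM, Tgfb1 108 ± 2.52 TPM and Il1a 89.7 ± 34.7 TPM. Il6 (chromosome 5, 30013114 to 30019981) was low at 2.52 ± 1.09 TPM. Tnf exceeded Il6 by 7.50 ± 0.11 on the log2 scale (limma, adjusted p = 2.42e-10, 3 of 3 libraries), the largest ratio of the 24 pairs. The anti-inflammatory cytokine gene Il10, at 24.7 ± 12.3 TPM, exceeded Il12b at 1.76 ± 0.121 TPM by 3.10 ± 0.24 (limma, adjusted p = 6.04e-06, 3 of 3 libraries). The receptor antagonist gene Il1rn, at 57.3 ± 13.3 TPM, was below Il1b, with a log2 ratio of -1.06 ± 0.13 (limma, adjusted p = 8.47e-05), and Il1b exceeded Il1a by 0.49 ± 0.11 (limma, adjusted p = 0.00267); both directions held in 3 of 3 libraries. Without random pairs in the fit the adjusted p of Il1b/Il1a was 0.102 (limma).

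Of 18 chemokine genes 15 were detected, with a median level of 6.43 (log2), above all random lists. Ccl5 was followed by Cxcl10, which attracts T cells through Cxcr3, at 604 ± 312 TPM, and by Ccl3 at 419 ± 145 TPM and Ccl4 at 405 ± 144 TPM, which attract monocytes and T cells. Ccl17, Ccl24 and Cxcl3 were below 1 TPM in each library. Ccl3 was below Ccl5 with a log2 ratio of -3.54 ± 0.18 (limma, adjusted p = 2.90e-07). Cxcl2, a neutrophil attractant at 173 ± 77.2 TPM, was below Cxcl10 with a log2 ratio of -1.80 ± 0.17 (limma, adjusted p = 1.96e-05). Both held in 3 of 3 libraries.

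**Figure D2:**
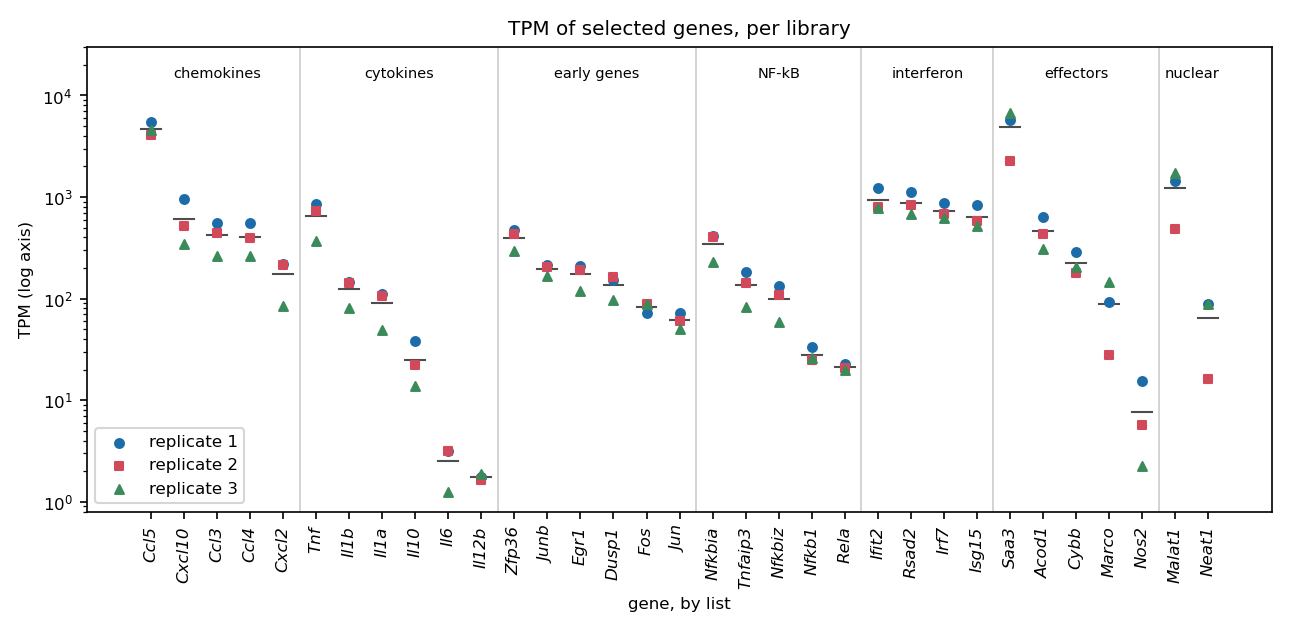
TPM of 33 genes on a log axis, grouped by list, with one symbol per library and a bar at the mean of 3 libraries. Tnf lies between 370 and 855 TPM and Il6 between 1.26 and 3.16 TPM; Malat1 and Neat1 are lowest in replicate 2.

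All 21 interferon-stimulated genes were detected, and their median of 7.44 (log2) was the highest of the 24 lists. Ifit2 (chromosome 19, 34550694 to 34576419), an antiviral RNA-binding protein gene, had 936 ± 256 TPM, the radical enzyme gene Rsad2 881 ± 224 TPM, the transcription factor gene Irf7 728 ± 134 TPM and the ubiquitin-like Isg15 642 ± 171 TPM. Ifit1 exceeded Irf1 by 0.72 ± 0.14 on the log2 scale (limma, adjusted p = 0.00110, 3 of 3 libraries). The interferon gene Ifnb1 itself, a list member named after its values were seen, had 2.95 ± 1.66 TPM.

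Antimicrobial and inflammatory effectors were uneven. Of 18 members 14 were detected. Saa3 led, followed by Acod1 at 458 ± 167 TPM, whose enzyme makes itaconate, the NADPH oxidase subunit gene Cybb at 225 ± 55.7 TPM and the superoxide dismutase gene Sod2 at 181 ± 41.0 TPM. Camp and Mmp9 were below 1 TPM in each library. Nos2, the inducible nitric oxide synthase gene, had 15.3, 5.64 and 2.24 TPM in replicates 1, 2 and 3, and Arg1, which competes for the same substrate, was below 0.1 TPM in each. Their log2 ratio was 2.74 ± 0.36 (limma, adjusted p = 0.000158, 3 of 3 libraries), and it depends on the pseudocount because Arg1 was near 0. The prostaglandin synthase gene Ptgs2 exceeded Ptgs1 by 2.82 ± 0.32 (limma, adjusted p = 6.87e-05, 3 of 3 libraries). The scavenger receptor genes Marco at 88.9 ± 59.4 TPM and Msr1 at 95 ± 19.2 TPM could not be ordered, with a log2 ratio of -0.37 ± 0.40 (limma, adjusted p = 0.408), which was -1.004 without replicate 3 (limma, adjusted p = 0.00654) and 0.30 without replicate 2 (limma, adjusted p = 0.272).

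Among 16 negative regulators of TLR signalling 14 were detected, with a median of 5.25 (log2), above all random lists. Zfp36, Dusp1 at 137 ± 35.7 TPM and Tnfaip3, which also belong to the lists above, led together with Trafd1 at 127 ± 23.2 TPM. Rnf125 and Sigirr were below 1 TPM in each library. Socs3 at 125 ± 38.4 TPM exceeded Socs1 at 2.81 ± 1.15 TPM by 5.05 ± 0.20 on the log2 scale (limma, adjusted p = 1.05e-07, 3 of 3 libraries); both encode suppressors of cytokine receptor signalling. Zfp36 exceeded Elavl1, whose product stabilises mRNAs of the same kind, by 4.30 ± 0.12 (limma, adjusted p = 1.03e-08, 3 of 3 libraries). The pseudokinase gene Irak3, at 14.2 ± 2.80 TPM, did not differ detectably from Irak1, at 13.3 ± 0.287 TPM (log2 ratio 0.08 ± 0.13; limma, adjusted p = 0.570). The p-values rest on the spread between these 3 libraries only, with each pair's variance drawn toward that of the random pairs. For pairs with a wide spread the SE is therefore smaller than their own libraries would give. Neat1/Gapdh, for example, had an SD of 1.32 and an SE of 0.41. A ratio of TPM between genes also carries differences in how well each gene's length and mappability are modelled, which replicates share.

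**Figure D3:**
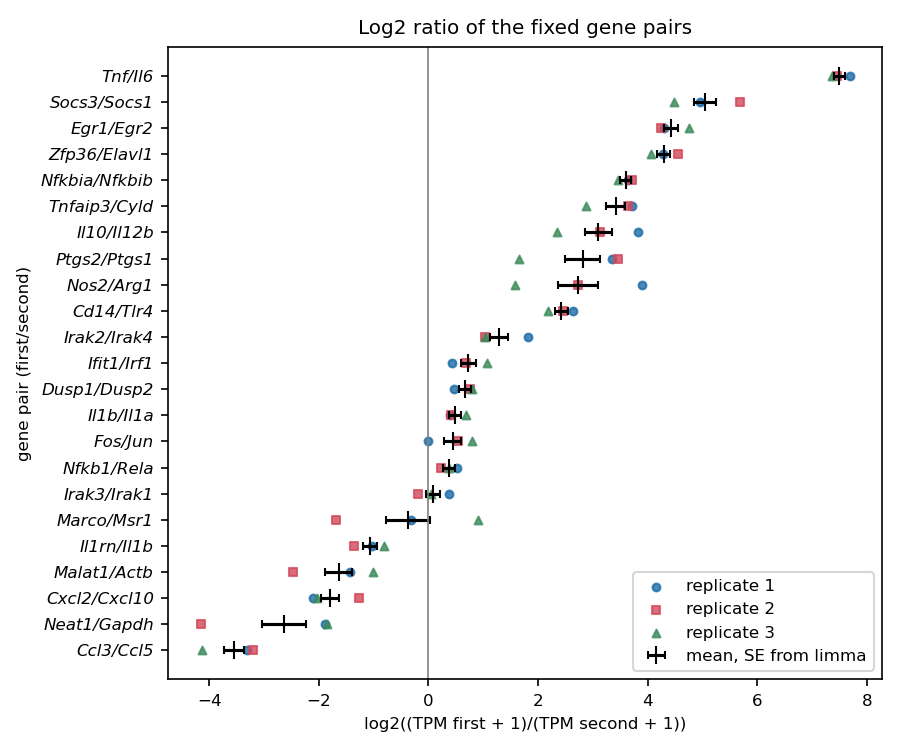
Log2 ratio of TPM for 23 of the 24 gene pairs fixed in advance, with one symbol per library and the mean with its SE from limma. Tnf/Il6 has the largest ratio, 7.50, and Irak3/Irak1 and Marco/Msr1 are the 2 pairs that did not pass the threshold of 0.05.

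All 23 components of the TLR4 pathway were detected, with a median of 3.80 (log2; 99.99 percentile of random lists, and 89.2 against detected protein-coding genes alone). Cd14, the co-receptor gene, had 130 ± 27.7 TPM, the kinase gene Ikbke 84.5 ± 31.5 TPM, Irf5 63.9 ± 8.601 TPM and the adaptor gene Myd88 52.0 ± 8.13 TPM. Cd14 exceeded the receptor gene Tlr4, at 23.0 ± 1.43 TPM, by 2.42 ± 0.12 on the log2 scale (limma, adjusted p = 2.71e-07), and Irak2 exceeded Irak4 by 1.29 ± 0.17 (limma, adjusted p = 0.000135), both in 3 of 3 libraries. Only 6 of 12 alternative activation genes were detected. Il4ra at 39.9 ± 9.997 TPM, Tgm2 at 26.5 ± 11.3 TPM, Mrc1 at 19.8 ± 1.72 TPM and Folr2 at 5.25 ± 0.614 TPM led that list, whereas Alox15, Arg1, Cd163 and Mgl2 were below 1 TPM in each library. Its median of 1.02 (log2) lay at the 69.3 percentile of random lists.

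Metabolic genes were detected almost throughout. All 18 glycolysis genes were detected (median 5.83, log2), led by Gapdh at 317 ± 13.3 TPM, Aldoa at 149 ± 10.3 TPM, Pkm at 145 ± 9.70 TPM and Hk3 at 116 ± 19.4 TPM. All 16 genes of the TCA cycle and respiratory chain were detected (median 4.96), led by Atp5b at 218 ± 16.7 TPM and Cox4i1 at 176 ± 9.83 TPM, with Atp5a1 at 86.0 ± 6.98 TPM and Sdhb at 67.9 ± 2.60 TPM. Of 15 genes of cholesterol and lipid handling 14 were detected (median 5.07), led by the lipoprotein gene Apoe at 1167 ± 245 TPM, the lipid droplet gene Plin2 at 205 ± 36.5 TPM, Lpl at 90.9 ± 16.2 TPM and the cholesterol exporter gene Abcg1 at 70.4 ± 4.03 TPM. All 13 stress genes were detected (median 5.01), among them the autophagy receptor gene Sqstm1 at 325 ± 99.1 TPM, the chaperone gene Hspa5 at 183 ± 45.1 TPM, Ppp1r15a at 178 ± 81.2 TPM and Ddit3 at 121 ± 33.1 TPM. Of 15 proliferation genes 7 were detected, with a median of 1.19 (76.2 percentile). With TPM rescaled over nuclear protein-coding genes, a total without 7SL RNA, 13 of the 15 reached 1 in all libraries. Pcna at 63.1 ± 4.40 TPM stood above Mki67 at 5.94 ± 2.07 TPM, Cdk1 at 5.74 ± 0.195 TPM and Top2a at 3.38 ± 0.367 TPM, and Bub1, Ccna2, Ccnb1 and Plk1 were below 1 TPM in each library.

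Long RNAs known to stay in the nucleus were not absent from the cytosolic libraries. Malat1 (chromosome 19, 5795690 to 5802672) had 1445, 485 and 1726 TPM in replicates 1, 2 and 3, and Neat1 (chromosome 19, 5824708 to 5845478), the scaffold of paraspeckles, had 87.7, 16.1 and 88.3 TPM. Malat1 was below Actb with a log2 ratio of -1.64 ± 0.25 (limma, adjusted p = 0.000334) and Neat1 below Gapdh with a log2 ratio of -2.63 ± 0.41 (limma, adjusted p = 0.000376), both in 3 of 3 libraries. Tug1 had 20.95 ± 4.35 TPM and Firre 2.80 ± 1.66 TPM, and Kcnq1ot1 was below 1 TPM in each library. No count fell on Meg3, Miat or Mirg, for which the upper 95% confidence bound is 3 counts per library. The median level of the 11 list members was 0.64 (log2). Of 9 cytoplasmic long RNAs matched by name 8 were detected, with a median of 3.18 (log2; 97.3 percentile, and 45.1 against detected protein-coding genes alone), led by Zfas1 at 50.1 ± 15.1 TPM, Gas5 at 47.8 ± 4.50 TPM, Snhg6 at 22.2 ± 4.92 TPM and Snhg8 at 10.8 ± 2.77 TPM; Dancr was below 1 TPM in each library.

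Several lists of inducible genes and the nuclear-retained long RNAs differed between replicates by more than matched lists, some of them because of 1 library. Without replicate 3 immediate early genes lay at the 8.94 and inflammatory cytokines at the 43.3 percentile of spread, and without replicate 2 nuclear-retained long RNAs lay at the 61.2 percentile. The biological coefficient of variation over 12752 genes was 0.189 (edgeR common dispersion), and it was 0.135 without replicate 2. No library was a second copy of another, with chi-square values of 81.8, 39.3 and 97.2 per degree of freedom for replicates 1 and 2, 1 and 3, and 2 and 3; separate preparations of one sample would exceed 1 as well. Deposited TPM of the median detected nuclear protein-coding gene differed from the mean of the other libraries by 0.23 on the log2 scale in replicate 1, -0.14 in replicate 2 and -0.09 in replicate 3. Deviations below are relative to that shift, and this comparison of each library with the other 2 was added after the data were seen. Of 4332 genes with a mean TPM of 10 or more, 196 had a highest TPM at least 2 times the lowest, 87 of them among 4130 nuclear protein-coding genes. Replicate 1 was highest in 73 of these 87; with TPM rescaled over nuclear protein-coding genes 44 had such a range, with replicate 1 highest in 17. The count over all genes, 196 with 3 libraries, was 84 without replicate 2, 115 without replicate 1 and 130 without replicate 3. Of 72 snoRNA, scaRNA and snRNA genes 67 had such a range. So did 14 of 46 long non-coding genes, which is 30.4% against 2.11% of nuclear protein-coding genes. Matched lists were drawn by level and not by RNA class. The percentile of the nuclear-retained long RNAs therefore cannot separate nuclear retention from being non-coding.

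In replicate 3 the inflammatory lists lay below the other libraries, while 3 detected neutrophil markers deviated by 0.39 (99.1 percentile, 1 of 3 lower), 7 proliferation genes by 0.23 (98.1 percentile) and genes of the TCA cycle and respiratory chain by 0.09 (99.2 percentile). The median deviation was -0.76 for 13 inflammatory cytokine genes, -0.57 for 15 chemokine genes, -0.51 for 20 immediate early genes, -0.45 for 13 stress genes and -0.32 for 16 NF-kB genes, each below all of 10000 expression-matched random lists. Of the immediate early genes 18 of 20 were lower in replicate 3; Tnf deviated by -1.005, Cxcl2 by -1.29, Nfkbia by -0.76 and Egr1 by -0.67, whereas Fos deviated by 0.25. Interferon-stimulated genes were higher in replicate 1, by a median of 0.33 with none of 21 members below the other libraries, and deviated by -0.14 in replicate 3 (16.5 percentile). Cytoplasmic long RNAs deviated by -0.21 in replicate 3, with 8 of 8 members lower, and by 0.24 in replicate 2. With TMM-normalized counts these were -0.09 and 0.10, within the matched lists. In the read-based table they were -0.23 (0.36 percentile) and 0.39 (100 percentile). Antimicrobial and inflammatory effectors deviated by 0.48 in replicate 1, -0.29 in replicate 2 and -0.24 in replicate 3.

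In replicate 2 the nuclear-retained long RNAs were lower, with a median deviation of -1.09 over 4 detected members, all 4 below the other libraries, against 0.33 in replicate 1 and 0.76 in replicate 3. In replicate 2 Neat1 deviated by -2.32 and Malat1 by -1.57, but Airn by only -0.62 at 1.11 TPM, and Tug1 by less than Airn. Firre, at 0.94 TPM there and not among the 4, deviated by -1.84. Saa3 and Marco, which encode secreted and surface proteins, also lay lower there, at -1.33 and -1.92. This did not hold for secreted proteins in general, since 15 chemokine genes deviated by a median of 0.27 in replicate 2, with 4 of them lower. Genes of the TCA cycle and respiratory chain had a median SD of 0.10 (log2), at the 0.07 percentile of matched lists on deposited TPM, but at the 29.75 percentile with rescaled TPM and at the 34.8 percentile without replicate 1. In all, 10 of 18 lists with at least 3 detected members had a median SD at or above the 95 percentile of matched lists, and 5 did without replicate 3.

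**Figure D4:**
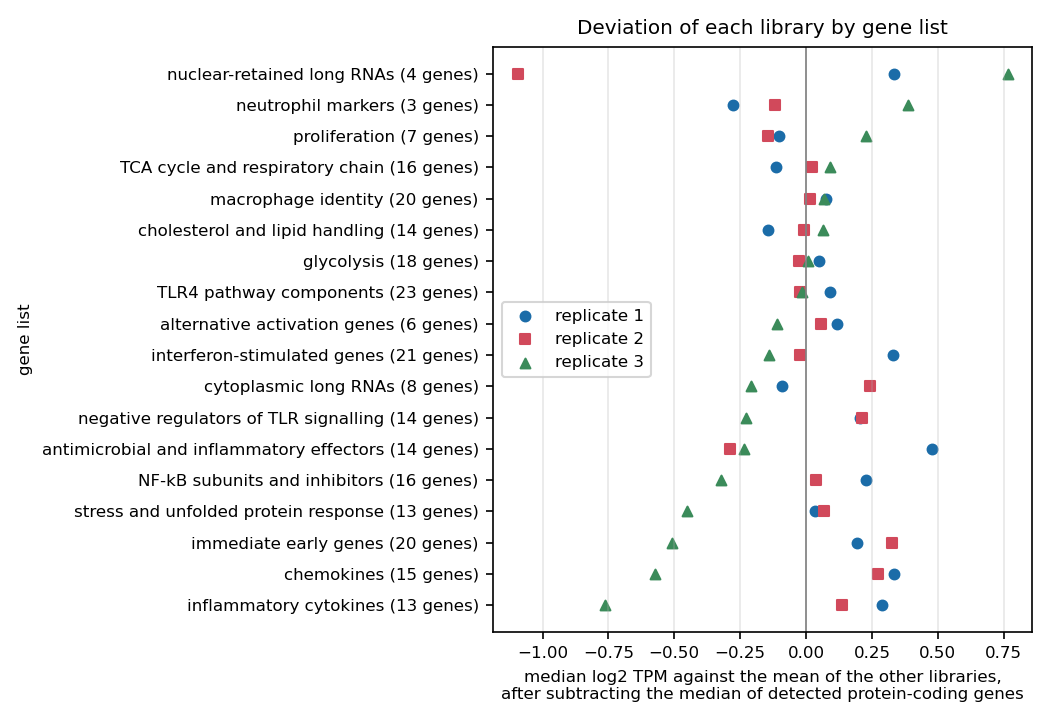
Median over detected list members of log2 TPM in one library against the mean of the other libraries, after subtracting the median of detected nuclear protein-coding genes. Replicate 3 lies at -0.76 for inflammatory cytokines and replicate 2 at -1.09 for nuclear-retained long RNAs.

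The 10 genes with the largest spread among all genes with a mean TPM of 10 or more were genes of short RNAs, mostly snoRNA and snRNA genes, namely Snord22, Gm23444, Gm23472, Gm26447, Rnu3a, Gm24497, Snora78, Gm25394, Gm14303 and Gm25791. Snord22 had 70, 25 and 55 expected counts but 1226, 0 and 0 TPM in replicates 1, 2 and 3, at a mean effective length of 0.347 bases. Its spread comes from the length correction. For the snRNA genes Gm23444 and Gm23472, with 558, 0 and 464 expected counts each, and Gm24497, with 4.5, 610 and 464, the spread lies in the assigned counts.

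The most abundant transcript was the same in both transcript quantifications for 24 of 25 genes examined, of which 2 have a single annotated transcript. The leading transcript of Il1rn, the receptor antagonist gene, took 71.3% ± 1.15 in the alignment-based table and 72.8% ± 1.20 in the read-based table (SD, n = 3). In the same order it took 83.4% ± 0.833 and 81.8% ± 0.292 for Pkm, 92.1% ± 1.37 and 88.1% ± 3.16 for Nfkbiz, and 98.1% ± 0.984 and 97.6% ± 1.30 for Myd88. Shares were split more evenly for Nfkb1 at 40.8% ± 7.01 and Ptprc at 42.3% ± 6.33, both alignment-based. The same transcript led at differing shares in the alignment-based and read-based tables for Mcl1 (94.6% ± 8.34 and 70.2% ± 12.0), Irak2 (64.4% ± 7.44 and 44.7% ± 14.5) and Irak1 (45.1% ± 1.31 and 34.1% ± 3.31). The leading transcript of Sod2 is annotated as a processed transcript and took 48.4% ± 3.11. The exception was Nfkb2, led by one protein-coding transcript at 44.8% ± 11.3 in the alignment-based table and by another at 46.7% ± 3.46 in the read-based one. Across 55536 genes, which are not independent replicates, gene sums of the transcript tables had a Spearman correlation of 0.813, and of 0.973 across the 9648 detected genes.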

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

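Of 6 tests in this part the 2 of nuclear RNA were chosen only after the pattern was seen. The tests of transcript length and of short transcripts were written down before their values were known.

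The row of phiX, a bacteriophage genome commonly added to sequencing runs as a control, lies outside the gene comparisons. It held counts far above 3, the upper 95% confidence bound for a count of 0. It took 0.356% of expected counts in replicate 1, 0.125% in replicate 2 and 0.104% in replicate 3, which is 136497, 58036 and 40288 counts.

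Replicate 2 was lower in nuclear-retained long RNAs. The deviations in this and the next paragraph are relative to all detected protein-coding genes, which removes any single factor per library by construction and is no test of scaling. Transcript length is argued against, since protein-coding genes matched on effective length and level deviated by a median of -0.0372, and 0.03% of matched random lists reached 0.5 times the list's value. This test is weak, because the list has 4 members and Malat1 is matched loosely. Few protein-coding genes are as abundant as Malat1 (Apoe, at 1167 TPM, ranked 18), and the 50 nearest genes were taken. Less nuclear RNA in the cytosolic fraction of replicate 2 stays open and is a candidate explanation: across 4129 genes, annotated retained-intron transcripts relative to protein-coding transcripts of the same gene deviated by a median of -1.47 (log2, read-based) in replicate 2, and 89.2% of the genes were below 0. Abundant non-coding RNAs were mixed on this point. 7SK RNA held 4.45%, 3.59% and 6.35% of TPM in replicates 1, 2 and 3, where nuclear protein-coding genes held 33.3%, 28.1% and 27.7%. Relative to those genes 7SK RNA was about level in replicates 1 and 2. Small nuclear RNAs, at 0.907%, 0.281% and 0.995%, were lowest in replicate 2. No biological explanation was tested, since the design has 1 group.

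Replicate 3 was lower in immediate early and NF-kB genes. Transcript length is argued against by a median of -0.0397 in protein-coding genes matched on effective length and level, where 0% of random matched lists reached 0.5 times the members' value. Less nuclear RNA in replicate 3 is argued against too, because retained-intron relative to protein-coding transcripts were higher in replicate 3 than in replicate 1 alone, by a median of 0.37 (log2, read-based) over 4129 genes and 0.27 (alignment-based) over 4275. A weaker or differently timed response of that culture is a possible explanation that was not tested, since no label separates the replicates.

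The quantifications gave protein-coding genes different shares of TPM, 29.7% ± 3.17 in the alignment-based table and 11.9% ± 1.13 in the read-based one. Short transcripts at 0 in the alignment-based table may account for much of this: 5 genes, the pseudogenes Gm12895 and Gm12896 and the microRNA genes Gm23935, Gm24245 and Gm24270, held 71.4%, 60.2% and 68.8% of read-based TPM in replicates 1, 2 and 3. Without them the median log2 ratio of read-based to alignment-based TPM over 9106 protein-coding genes moved from -1.04 to 0.28. Leaving out genes with so large a read-based share raises this ratio by construction, so the rise itself is no support. Protein-coding genes then held 42.6%, 32.4% and 34.3% of read-based TPM in replicates 1, 2 and 3. In the alignment-based table they held 33.3%, 28.1% and 27.7%, so the difference was reversed. Leaving out every transcript under 400 bases brought the shares to within 1.37 percentage points, but both then exceeded 90%, so that test had no room to differ and transcripts shorter than the read pairs cannot be told apart from the 5 genes as the source.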

How the results depend on the processing

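The alternatives that rescaled TPM for detection and for the pairs, that centred log2 values for list spread, and that recomputed list deviations were chosen after the data were seen; the others were fixed before. With each library left out in turn, detected genes ranged from 9702 to 10061, the coefficient of variation from 0.135 to 0.236, genes with a 2-fold range from 84 to 130, pairs past the threshold from 21 to 22, lists at or above the 95 percentile of spread from 5 to 10, isoform matches from 23 to 24, the correlation of the quantifications from 0.807 to 0.821 and the protein-coding share of TPM from 27.9% to 30.7%. Lists at or above the 95 percentile of level stayed at 14, but were 11 against detected protein-coding genes alone, where inflammatory cytokines lay at the 51.9, TLR4 pathway components at the 89.2 and cytoplasmic long RNAs at the 45.1 percentile. Leaving out replicate 3 gave the lowest count of lists by spread, 5 against 10, and leaving out replicate 2 the lowest coefficient of variation.

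A TPM minimum of 5 gave 5967 detected genes against 9648, and TPM rescaled over nuclear protein-coding genes gave 11380. The coefficient of variation was 0.0848 by the median gene-wise dispersion of DESeq2, a median over genes and not a common value, against 0.189. Genes with a 2-fold range numbered 825 at a mean TPM of 1 or more, 89 at 50 or more and 120 with TMM-normalized counts, against 196. The correlation of the quantifications was 0.973 over detected genes against 0.813. Nuclear protein-coding genes held 86.8% of expected counts and 11.9% of read-based TPM, against 29.7% of TPM. The minimum and the unit set these changes by construction; for the others the cause was not tested.

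Among pairs, 208 of 216 alternative values kept their side of the threshold and none changed sign with a call. The exceptions were Il1b/Il1a, Nfkb1/Rela and Fos/Jun without random pairs in the fit (limma, adjusted p = 0.102, 0.187 and 0.162), Nfkb1/Rela read-based or without replicate 1, Fos/Jun without replicate 2 or 3, and Marco/Msr1, which passed without replicate 3 at a log2 ratio of -1.004 (limma, adjusted p = 0.00654) and was 0.30 without replicate 2. With the read-based table or TMM-normalized counts, 10 list deviations no longer lay beyond the matched lists, such as negative regulators in replicate 3 (0.33 to 10.7 percentile, read-based), 3 came to do so, and none beyond them changed sign. Depth did not limit the abundant genes, but Arg1 rests on 6, 0 and 3 counts. No paired analysis was possible because the libraries form 1 group.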

Other observations

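The comparison of retained-intron transcripts below was chosen only after the result was seen. Rgs1, a regulator of G protein signalling, had 382, 421 and 112 TPM in replicates 1, 2 and 3, and Tnfsf9, the ligand of the costimulatory receptor 4-1BB, had 59.3, 74.5 and 18 TPM. Slc13a3, a carrier of dicarboxylates, had 32.2, 6.41 and 31.0 TPM, a profile like that of Marco at 92.2, 27.9 and 146 TPM. The chemokine gene Cxcl1 was also highest in replicate 2 and lowest in replicate 3, with 16.9, 34.1 and 6.77 TPM. These genes are among the 15 nuclear protein-coding genes with the largest spread at a mean TPM of 10 or more, chosen after their values were seen, so that they differ between libraries by their choice.

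Gm49369, a protein-coding gene model that overlaps Ctsd, had 17.3, 436 and 550 TPM in replicates 1, 2 and 3 in the alignment-based table, but 8.94, 54.7 and 36.7 TPM in the read-based one. The long non-coding gene Gm26917 (chromosome 17, 39843013 to 39846341) had 1852, 236 and 1402 TPM. Small nuclear RNAs held 0.907%, 0.281% and 0.995% of TPM in replicates 1, 2 and 3, and mitochondrially encoded RNAs 0.469%, 0.229% and 0.552%.

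Between pairs of libraries, retained-intron relative to protein-coding transcripts of the same genes were lower in replicate 2 than in replicate 1 by a median of -1.29 (log2, read-based; 85.6% of 4129 genes below 0) and than in replicate 3 by a median of -1.67 (91.2% below 0). The alignment-based table gave -1.25 and -1.58 over 4275 genes. The 4 nuclear-retained long RNAs differed by a median of -0.94 between replicates 2 and 1, and by 0.17 between replicates 3 and 1, where 1 of them was lower.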
